A study of Mus musculus with 30 samples.

How the data were processed

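Genomic DNA of 9 primary clones, 20 tertiary clones and unmodified R1 cells was labelled with Cy5 and reference DNA of C57BL/6J mice with Cy3, per the labels, in 1 dye orientation. Cells were grown on gelatin, per the labels' protocols. The authors deposited, for each array, a quantification file per channel, with the mean intensity of each spot, the mean intensity of its local background and a flag, per the file headers. Headers name software version 4.1 on 24 arrays and version 6.0.1 on 6 arrays. The deposited series table holds log2 ratios for 6507 BACs. Its column medians lay between -0.067 and 0.125. Its correlation with the log2 ratio of the deposited intensities of the same array lay between 0.764 and 0.997, which gave its direction. How the authors normalized or filtered that table is not given in the sources used here.

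For the main values, the foreground intensities were used as given, without background subtraction, as log2 of Cy5 over Cy3. Of the 21168 spots per array, the 1152 named empty, the 432 without a name and all spots with a flag in either channel were left out, which left between 6884 and 15275 spots. Each array was centred on the median of its log ratios and the spots of a BAC were averaged. No loess or quantile step was applied. The median signal over local background lay between 2.31 and 7.80 for Cy5 and between 3.44 and 8.48 for Cy3. The SD between spots of 1 BAC on an array had a median between 0.0391 and 0.0816. This covers noise within an array only, and p-values measure the spread between arrays of different clones, since each clone has 1 array.

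Scan dates and software versions in the file headers divide the arrays into 3 scan batches of 6, 18 and 6 arrays. Batch 3 holds all 6 male-reference arrays (5 tertiary clones and R1) and no other, so a fit of the reference's sex with batch as a block could not be made. Batch 1 holds 2 primary and 4 tertiary clones, and batch 2 holds 7 primary and 11 tertiary clones. Per the file headers, spots were segmented by the method named auto on all arrays of batches 1 and 3 and, in batch 2, on the 2 arrays of clones 7 and 2-22, and by fixed circles on the other 16.

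Tests were run with limma 3.58.1 in R 4.3.3, with array weights from a fit of 1 mean per BAC over all arrays and Benjamini-Hochberg adjustment. A BAC was called at an adjusted p under 0.05 and an absolute log2 difference of at least 0.3. Male-reference minus female-reference arrays, all 30 arrays against 0, and tertiary minus primary clones with family as a block were fitted as groups. A single clone was set against its primary clone or R1 with 1 coefficient for each of the 2 arrays and a common mean for the others, which gave the spread, and each primary clone was set against the mean of the other 8. BACs had to be measured on at least 50% of the arrays of each group, a rule set after the files were seen. BACs called with the reference's sex were left out of the comparison with the strain, of tertiary against primary clones, of pairs whose references were not both labelled with the same sex, and of the comparison with R1. Group names come from the labels.

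BACs were to be named by size among those called, the 10 largest in each direction for group results and the 3 largest for single clones. Because no table paired the BACs with genes, at most 2 in each direction are named per comparison. Chromosome dosage, contiguous segments and the preset lists of pluripotency, growth control and strain-variable genes need BAC positions and are not analysed here. No cell type markers apply to genomic DNA. The main design, the naming rule and most of the other settings were fixed before the data were examined. These settings were background subtraction, normexp with offset 50, loess, the deposited table centred on each column's median, removal of spots under 2 times the local background, no array weights, thresholds of 0.2 and 0.5, other blocks, and leaving out families or arrays.

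The tests were tried on simulated data with 200 changed BACs and the real missing values. Noise was drawn independently from a normal distribution with each BAC's SD over arrays, scaled by the array weights. Batch effects and correlation between arrays or BACs were not simulated, so recovery on the real arrays may differ. Changing 200 BACs at once also eases the Benjamini-Hochberg threshold, so a smaller set of changed BACs would be recovered less often. At a log2 difference of 0.45 between reference sexes, 93% were recovered among 3474 BACs, with 4 false calls. Random lists, 10000 per test, were matched to a set in number and mean intensity. Overlaps and lists used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.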

Results

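Genomic DNA from mouse embryonic stem (ES) cells was compared with reference DNA of a normal C57BL/6J mouse on 30 arrays of bacterial artificial chromosome (BAC) clones. The cells were the male ES line R1, of 129 strain background, and clones made from it. The 9 primary clones carried an anchor retrovirus selected with puromycin. The 20 tertiary clones came from these primary clones after a further retrovirus, selected with hygromycin, and Cre-mediated recombination, selected with G418. This retroviral scheme was built to make chromosomal deletions. Unmodified R1 cells gave 1 array. Passage numbers ran from 24 to 26 in primary and from 29 to 35 in tertiary clones. Each clone was hybridised once, so no value of a single clone has a replicate of its own. The reference mouse was female on 22 arrays, male on 6 arrays, and of unstated sex on the arrays of clones 6-36 and 7-30.

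Each array held 6523 BACs, nearly all printed as 3 spots. Of these, 6418 came from the RP23 library and 105 from the RP24 library. After the spots marked by the quantification software were left out, between 2603 and 5501 BACs per array had a value, with a median of 3630. The number of arrays limits the precision of every value below. Genomic positions of the BACs were not used here, so results are given by BAC and not by gene or chromosome.

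The arrays with a male and with a female reference were compared to see how a known difference in sex chromosome number appears on this platform. A clear set of BACs fell when the reference was male. Of 3474 BACs tested, 96 were lower and 132 were higher with a male reference. All but 1 of the 96 lower BACs belonged to the RP24 library, which was made from a male mouse, while the RP23 library was made from a female. Of the 103 RP24 BACs tested, 95 were lower and 8 were not called, an excess over the 3371 other BACs with p = 3.60e-175 by Fisher's exact test, 2-sided, across BACs. The lower BACs had a median log2 difference of -3.09 (SD 1.11 over BACs) and the higher BACs one of 0.42 (SD 0.12).

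The BACs with the greatest falls were RP24-177B22, at a log2 difference of -4.90 (SE 0.47, limma adjusted p = 8.69e-10), and RP24-190C12, at -4.47 (SE 0.43, adjusted p = 1.03e-09). The greatest rises were those of RP23-178F12, at 0.84 (SE 0.073, adjusted p = 6.21e-10), and RP23-319G18, at 0.81 (SE 0.083, adjusted p = 3.00e-09). A male reference carries 1 X and 1 Y chromosome, as the ES cells do by their label. With local background subtracted the split turned to 104 higher and 245 lower. The 6 male-reference arrays were also the 6 arrays of the last scan batch, so the reference's sex and the batch cannot be told apart.

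Single arrays showed how steady these sets were, and 3 clones stood apart. On 21 of the 22 female-reference arrays the median log2 ratio of ES cell to reference DNA over the RP24 BACs lay between 2.00 and 2.87. Clone 9-62, also with a female reference, had a median of -0.016 (SD 0.15 over 98 BACs). Clone 6-36, whose reference sex was not given, had 0.036 (SD 0.13 over 76 BACs), whereas clone 7-30, the other array without this label, had 2.78 (SD 1.23 over 103 BACs). On 5 of the 6 male-reference arrays the median lay between -0.25 and -0.13, and on that of clone 9-37 it was -2.86 (SD 1.25 over 98 BACs).

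The BACs that were higher with a male reference did not move with the RP24 BACs in these clones. Their median log2 ratio, over BACs chosen without the array in question, lay between -0.49 and -0.17 on the other 21 female-reference arrays. It was -0.38 (SD 0.25) in 9-62 and -0.29 (SD 0.28) in 6-36. On the other 5 male-reference arrays it lay between -0.054 and 0.086, and it was 0.044 (SD 0.18) in 9-37. Over all BACs, the array of 9-37 correlated with the female-reference arrays at r between -0.883 and 0.030. Without the RP24 BACs these correlations, taken across BACs that are not independent replicates, lay between -0.074 and 0.336. The dyes are stated in the labels, so the direction of this array was kept.

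**Figure D1:**
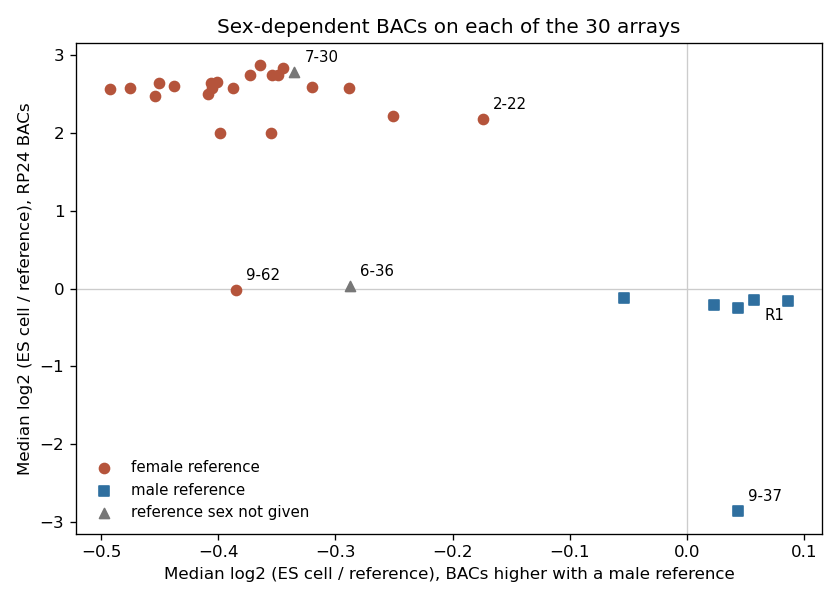
Each point is 1 array. The horizontal axis gives the median log2 ratio of ES cell to reference DNA over the BACs that were higher with a male reference, chosen without that array where it entered the comparison, and the vertical axis the same median over the RP24 BACs. Clone 9-62 lies at -0.016 on the vertical axis, far from the other female-reference arrays (2.00 to 2.87), and clone 9-37 at -2.86, far below the other male-reference arrays (-0.25 to -0.13).

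The ES cells were then compared with the reference strain, which sets 129 cells against C57BL/6J DNA. Leaving out the BACs called with the reference's sex, 19 BACs were higher and 87 lower in the ES cells over the 30 arrays, among 3396 tested. RP23-271O20 fell by 0.93 on the log2 scale (SE 0.031, limma adjusted p = 7.04e-26) and RP23-293K19 fell by 0.80 (SE 0.028, adjusted p = 1.60e-25). RP23-220L16 was higher by 0.64 (SE 0.033, adjusted p = 3.76e-20) and RP23-450M22 by 0.55 (SE 0.023, adjusted p = 7.35e-23). Among the BACs called with the reference's sex, the medians on female-reference arrays were 2.61 for RP24 and -0.36 for the others.

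All arrays had the same dye orientation, so a constant dye effect and a difference in copy number cannot be told apart here. The arrays share cell line and reference strain, and their p-values cover the spread between arrays only. With loess normalization the split was 18 higher and 42 lower, and scan batch 1 alone gave 202 higher and 97 lower.

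Tertiary clones as a group were compared with the primary clones from which they came, to find changes that recurred across families. The BACs called with the reference's sex, which include most RP24 BACs, were left out of this test. The low RP24 ratios of single tertiary clones described above could therefore not appear in it. Among the other BACs, none was called higher or lower of 3144 tested with limma and clone family as a block. The estimated log2 differences lay between -0.22 and 0.24, with a median SE of 0.042, and the lowest adjusted p was 0.405. At an unadjusted p under 0.05 there were 185 BACs, where 157.2 were expected. With scan batch as a block, within scan batch 1 and within scan batch 2 the count was 0 as well. In data simulated with independent noise, 93.5% of BACs changed by 0.4 on the log2 scale in every tertiary clone were recovered among 3370 tested. Under such noise, without a batch effect and with 200 BACs changed at once, a shift of that size common to the tertiary clones would mostly have been called.

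Each tertiary clone was next compared with its own primary clone, to find anomalies absent from the primary clone. Calls were few, and no BAC was called in more than 1 pair. Over the 20 pairs, 9 BACs were called higher and 11 lower, in 59304 tests. Clone 1-13 had 6 lower BACs and clone 13-34 had 4, with 1 more in clone 14-32. Higher BACs were called in 2-22 (3 BACs), 4-39 (3 BACs), 13-34 (2 BACs) and 9-62 (1 BAC).

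In clone 1-13, RP23-455J9 fell by 0.95 on the log2 scale (SE 0.18, limma adjusted p = 0.015) and RP23-401K5 fell by 0.91 (SE 0.13, adjusted p = 0.000128). In clone 13-34, RP23-55M6 fell by 0.80 (SE 0.10, adjusted p = 2.00e-05) and RP23-313D9 fell by 0.70 (SE 0.10, adjusted p = 0.000299), while RP23-39C11 was higher by 0.57 and RP23-356D8 by 0.54. RP23-356D8 lost its call under all 5 alternative scalings, filters and weights that gave it a value, and RP23-39C11 with loess and without array weights. With scan batch as a block both kept their calls. In clone 14-32, RP23-316K5 fell by 0.84 (SE 0.13, adjusted p = 0.00185). In clone 2-22, RP23-144F16 was higher by 1.23 (SE 0.25, adjusted p = 0.044) and RP23-293K19, one of the BACs lower against the reference strain, by 0.77 (SE 0.15, adjusted p = 0.0371). The calls of both these BACs in 2-22 were lost with loess, with normexp, with local background subtracted, without array weights and in the authors' deposited values, at log2 differences between 0.77 and 1.34. The spots of 2-22 were segmented by another method than those of primary clone 2, so this pair alone cannot tell the clone and the method apart. On the other arrays with the method of 2-22, RP23-144F16 lay between -0.33 and 0.46, against 1.33 in 2-22. RP23-293K19 lay between -1.08 and -0.52 there, against -0.20 in 2-22. The method thus did not give such values on other arrays. Other ratios of 2-22 also lay nearer to 0, however. RP23-271O20 was at -0.44 in 2-22 and -0.49 in clone 7, against -0.94 in primary clone 2. The BACs higher with a male reference had in 2-22 the median nearest to 0 of the female-reference arrays, -0.17. How much of the move of RP23-293K19 towards 0 is specific to this BAC therefore cannot be told. In clone 9-62, RP23-436M8 was higher by 0.87 (SE 0.17, adjusted p = 0.0489). In clone 4-39, RP23-211O9 was higher by 0.86 (SE 0.14, adjusted p = 0.00858). This difference came from primary clone 4, whose log2 ratio for RP23-211O9 was -0.89, against -0.029 in 4-39. Calls of RP23-455J9, RP23-313D9 and RP23-211O9 in these pairs were lost without array weights, and those of RP23-316K5, RP23-436M8 and RP23-211O9 with local background subtracted. The call of RP23-436M8 was also lost in the deposited values (0.74) and with dim spots left out (0.83).

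The loss of RP24 signal in 9-62 did not appear among these calls, because the spread was taken over arrays of both reference sexes. When it was taken over female-reference arrays only, a choice made after seeing the data, 69 of 98 RP24 BACs were called lower in 9-62 than in primary clone 9, with a median log2 difference of -2.04. No RP24 BAC was called in the other 12 pairs that share a reference sex, where the median RP24 difference ran from -0.44 in 14-32 to 0.59 in 9-35. In those pairs the spread included the array of 9-62, which widened it for RP24 BACs. The lack of calls there therefore cannot show that 9-62 alone differed.

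These pairs were compared on 1 array each, which limited what could be called. In simulated data, 85.4% of BACs raised by 0.58 on the log2 scale were recovered in 13-34, 61.9% in 2-41 and 28% in 14-39, and at a fall by 1 the shares were 99.5%, 96.4% and 87.4%. Both sizes exceed 0.42, the median difference of the BACs higher with a male reference. Recovery at that size was not simulated for pairs, so these shares may be too high for such changes. They may also be too high because 200 BACs were changed at once, where the real pairs had far fewer calls. Adjusted over all 20 pairs together, 6 of the calls were left. Set against all arrays outside the family in place of the primary clone, the tertiary clones had 162 higher and 59 lower BACs, among them 25 lower in 1-13 and 76 higher in 10-21. Other scalings moved the split of the pair calls: it was 22 higher and 115 lower with local background subtracted, and 10 higher and 20 lower with normexp. Of the 20 main pair calls, 10 were among the former and 15 among the latter. Only 4 were kept without array weights.

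Primary clones were compared with unmodified R1 cells to assess their genomic integrity. Almost nothing passed the test. In 25670 tests over the 9 clones, only RP23-248O24 was called, which fell by 0.81 on the log2 scale (SE 0.14, limma adjusted p = 0.0178) in clone 2. At an unadjusted p under 0.05 there were 1188 values, where 1283.5 were expected. With scan batch as a block no BAC was called, with limma again. R1 was scanned in another batch than all 9 primary clones and had a male reference. In simulated data for clone 13, 51.8% of BACs raised by 0.58 on the log2 scale and 96.0% of those lowered by 1 were recovered. There 200 BACs were changed at once, which eases the Benjamini-Hochberg threshold, so a smaller set would be recovered less often. Changes as small as 0.42, the median difference of the BACs higher with a male reference, were not simulated here. On the real arrays, the 20 BACs found below to be higher in clone 13 were not called against R1. Relative to the arrays outside its family, their median log2 was 0.66 in clone 13 and 0.026 in R1. The comparison with R1 thus missed differences of that size.

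Primary clones were also compared with one another, and clone 13 differed from the rest. In clone 13, 20 BACs were higher than in the other 8 primary clones and none was lower. RP23-318H16 was higher by 0.85 on the log2 scale (SE 0.10, limma adjusted p = 0.00015), and the median over the 20 BACs is given next. Relative to the arrays outside this family, the median of the 20 BACs was 0.66 (SD 0.12 over BACs) in clone 13, 0.60 (SD 0.17) in clone 13-34 and 0.63 (SD 0.14) in clone 13-42. On the 27 arrays of other families and R1 it lay between -0.15 and 0.086.

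The other calls among primary clones were 8 lower BACs in clone 7 and 7 in clone 9, all from the RP24 library, 1 lower BAC in clone 4 and 1 higher BAC in clone 6. RP24-354A24 fell by 1.62 in clone 7 on the log2 scale, a call lost with loess and in the deposited values, and RP24-234C23 fell by 1.40 in clone 9, where it was not called with local background subtracted (-0.53). Clone 9 had the lowest Cy5 signal over background, 2.31, and its RP24 median moved from 2.00 to 3.02 with background subtracted, so its lower RP24 values, and the size of the fall in 9-62 from clone 9, depend on the scaling. The array of clone 7 shared its segmentation method, within scan batch 2, with that of 2-22 alone. Relative to the 14 other female-reference arrays of that batch, a test chosen after seeing the data, the 8 BACs lower in clone 7 had a median log2 of -1.09 (SD 0.31) in clone 7 and -0.99 (SD 0.44) in 2-22. On those 14 arrays it lay between -0.13 and 0.13, so these calls are not specific to clone 7. The arrays of scan batch 1 have the same method as clone 7. There the median was -0.055 in 14, -0.011 in 9-35, 0.015 in 14-39, -0.28 in 14-32, -0.46 in 9 and -2.79 in 9-62. The fall thus did not follow the method in every batch. RP23-211O9 fell by 0.76 in clone 4 (SE 0.10, adjusted p = 0.0109), and RP23-230O8 was higher by 0.59 in clone 6 (SE 0.10, adjusted p = 0.0304). Neither call was kept without array weights, that of RP23-211O9 was also lost with local background subtracted and that of RP23-230O8 with normexp and loess. Neither clone had a call within scan batch 2. Clones 1, 2, 10 and 14 had no call. Within that batch, clone 13 had 19 higher BACs and clone 7 had 4 higher and 28 lower. The split over all primary clones, 21 higher and 16 lower, was 58 and 23 with loess normalization and 15 and 30 with normexp.

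**Figure D2:**
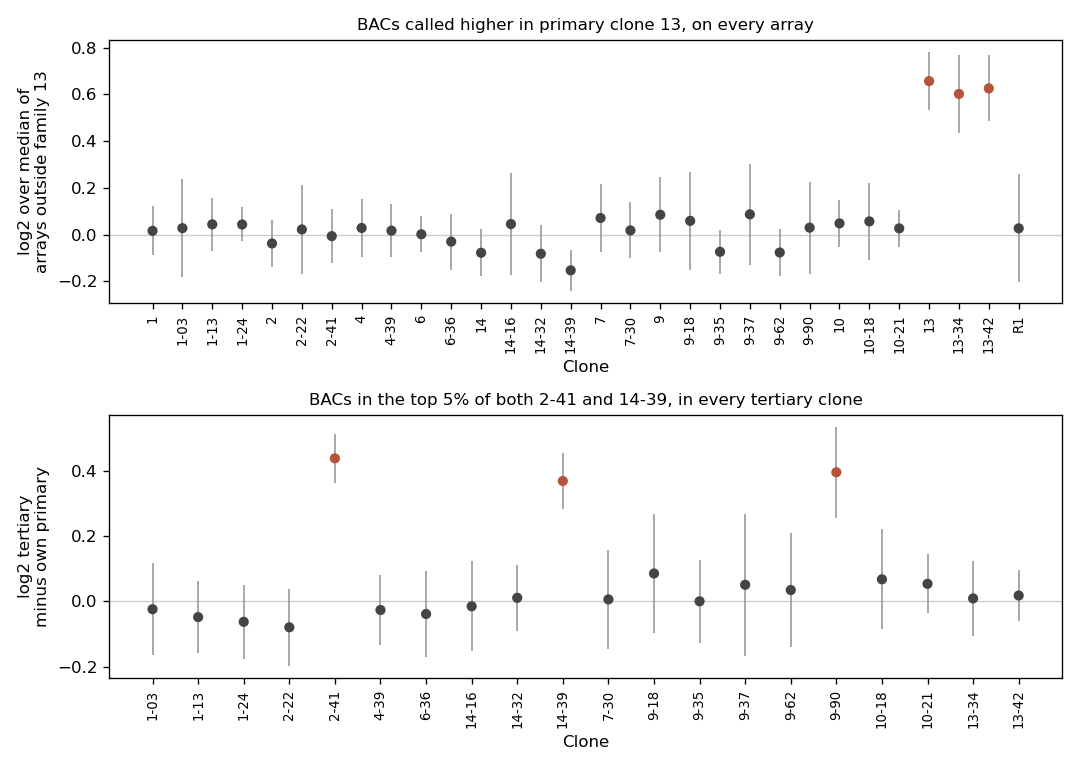
The upper panel gives, for each array, the median log2 ratio of the 20 BACs called higher in primary clone 13, relative to the median of the arrays outside that family. The lower panel gives, for each tertiary clone minus its own primary clone, the median of the 72 BACs that were in the top 5% of both 2-41 and 14-39. Bars are 1 SD over BACs. Clones 13, 13-34 and 13-42 lie between 0.60 and 0.66 in the upper panel, and 2-41, 14-39 and 9-90 between 0.37 and 0.44 in the lower one.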

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

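The tests in this part were chosen after the patterns had been seen, except those of print position, of loess and of other splits of the arrays. Outliers were sought in 19 combinations of a group and a measure, and 6 values were found. Chance gives about 1 in 20 for independent continuous values. Some measures were counts of calls, where a single call is flagged, and some followed the same signal. The 6 values are therefore no test of an excess over chance.

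Among the 6 male-reference arrays, clone 9-37 lay far below the others in the median log2 ratio of the RP24 BACs, at -2.86, where the next lowest was -0.25. Clones 9-62 (-0.016) and 6-36 (0.036) lay below the 21 female-reference arrays other than 9-62, the lowest of which was at 2.00. A reference or cell sample of the other sex would bring the BACs that are higher with a male reference near 0 in 9-62 and 6-36, and a dye exchange with a female reference would bring them to 0.2 or above in 9-37, but their medians were -0.38, -0.29 and 0.044, which argues against both. Dim hybridisation is argued against too, in 9-62 and 6-36 since the female-reference arrays, 9-62 aside, with less Cy5 signal over background had RP24 medians of at least 2.00, and in 9-37 since dim signal moves ratios towards 0 and its median was -2.86. Loss of male-specific DNA, such as that of a Y chromosome, from these clones is a candidate explanation, as a hypothesis, and spots outside the RP24 set bear on it: the empty-named spots described next had a median of 0.0997 in 9-62 (5 spots), -0.0965 in 6-36 (3 spots) and -2.36 in 9-37 (9 spots). The places of these BACs on the chromosomes were not tested.

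Signal appeared in spots named empty, which enter no comparison. Of the 1584 empty or unnamed spots, 9 carried unflagged signal on at least 15 arrays. Their median log2 ratio was 2.26 over the 21 female-reference arrays other than 9-62, with a range from 1.58 to 2.39, and lay between -0.11 and -0.080 on 4 male-reference arrays. Clone 9-37 was an outlier among the male-reference arrays in these spots as well, at -2.36. Primary clone 9 was an outlier among primary clones, at 1.58, where the others lay between 2.05 and 2.39.

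Primary clone 13 had 20 BACs higher than in the other primary clones, where the others had at most 1. A single faulty hybridisation is argued against by the separate arrays of 13-34 and 13-42, in which the lower of the medians of these BACs was 0.60. The BACs lay in 16 print blocks, and the most crowded block held 4, against 4 at the 99th percentile of random lists, so the block count decides nothing. All arrays have the same layout, and on arrays outside the family the median was at most 0.0864. This argues against a position effect shared by all arrays. One limited to the arrays of 13, 13-34 and 13-42 stays open. A copy gain carried by this clone family is a candidate explanation, as a hypothesis: the highest median of these BACs on an array outside the family was 0.0864.

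Primary clone 9 also had the highest SD between spots of a BAC among primary clones, 0.0816, where the others lay between 0.0512 and 0.0637. Primary clone 2 had 1 BAC lower than in R1, where the other primary clones had 0.

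For the comparison of reference sexes, 1 of 100 splits of the 28 arrays, the real one, gave as many calls: the real split gave 228 and the highest of the others 18, so chance can be excluded, while scan batch 3 cannot. For tertiary against primary clones the real count was 0, which every one of the 100 splits within families reaches by construction, and the highest of the others was 1, so the splits decide nothing for that count. At an unadjusted p under 0.05, 27 of the 100 splits, the real one included, gave at least the 185 BACs of the real split, and the highest of the others was 423, so chance cannot be excluded for these.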

How the results depend on the processing

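The tests with scan batch in single-clone fits, with the spread of 1 reference sex, on BACs measured on at least 24 arrays, within batches for clones, with segmentation as a block, and with 9-37 and 9-62 left out were chosen after seeing the data. So were those with female references of scan batch 1 or 2 only, and those on only the pairs that share a reference sex or scan batch. The count of tertiary against primary clones was 0 under all 24 alternatives, among them the fit with no replicate block and leave-one-out of each family (0 to 0). BACs called with the reference's sex were left out of that comparison, so its count does not cover the RP24 BACs among them. No replicate numbers pair the groups. The reference sex count, 228, lay between 186 (dim spots left out) and 331 (threshold of 0.2) under 16 of 18 alternatives, and leaving out each male-reference array gave 218 to 276. It was 349 with local background subtracted and 132 at a threshold of 0.5.

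With local background subtracted, the strain count became 262, that of the tertiary pairs 137, of primary clones against R1 6 and of primary clones against one another 94. These included 10 of the 20 main pair calls, 0 of the 1 against R1 and 24 of the 37 among primary clones. With normexp the R1 count was 2. With loess the strain count was 60, the pairs had 48 and the primary clones 81. With the authors' deposited values these counts were 61, 41 and 74, and that against R1 was 0. Without dim spots, without array weights, with scan batch as a block and with BACs measured on at least 24 arrays the R1 count was 0. Without array weights the pairs had 12 calls and the primary clones 57. Only 4 of the 20 main pair calls and 24 of the 37 main calls among primary clones were among these. The calls in single clones thus changed in identity as well as in number. The strain count was 430 at a threshold of 0.2, 8 at 0.5 and 299 in scan batch 1 only. The pairs had 221 calls against all arrays outside the family, 6 adjusted over all pairs together, 34 with scan batch as a block, and 84 with the spread from arrays of the same reference sex, in the pairs that share it. The cause was not tested.

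For the named BACs, 139 of 182 values kept their call, 43 lost it and 0 changed direction. All 43 losses fell on BACs named for single clones, since every BAC named for the reference sex and the strain kept its call throughout. The pooled share therefore overstates how steady the single-clone calls were. Settings in which a BAC had no value are not counted. The RP24 median, negative with a male reference, became 0.15 with background subtracted and 0.00413 with loess in clone 14-16, 0.0135 with background subtracted and 0.03 in the deposited values in clone 9-18, and 0.0171 with background subtracted in clone 1-03. The lowest median Cy5 signal over background was 2.31, in primary clone 9. A median signal in place of the mean, a batch block for the reference sex, chromosome dosage and segments were not run, because the columns, the design or the positions did not allow it.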

Other observations

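The tests in this part were chosen after the result was seen, except those of print position and loess. Tertiary clones of different families shared many of the BACs with the highest differences from their primary clones. No BAC was called higher than in the primary clone in 2-41, 14-39 or 9-90, so these lists rest on rank alone. Against all arrays outside the family, some BACs were called higher in 2-41 and 9-90, but none in 14-39. The 163 BACs with the highest difference from the primary clone were taken in 2-41 and in 14-39, among 3270 measured in both, and 72 were in both lists, where independent lists share 8.13. Over these 72 BACs the median log2 difference from the own primary clone was 0.44 (SD 0.074 over BACs) in 2-41 and 0.37 (SD 0.086) in 14-39. In 9-90, of a further family, it was 0.40 (SD 0.14, 66 BACs), but 9-90 was singled out because its highest BACs overlapped those of both clones, so this value is no separate test. In the other 17 tertiary clones it lay between -0.080 and 0.0858, so the sister clones 2-22, 14-16, 14-32, 9-18, 9-35, 9-37 and 9-62 did not show it.

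These 3 clones lie in 3 scan batches, and the highest median over the other tertiary clones, 0.0858, argues against scan batch as the cause. The most crowded print block held 7 of the 72 BACs, against 8 at the 95th percentile of random lists, which argues against print position. After loess the median in 9-90 was 0.36, which argues against a brightness-dependent dye effect. The cause of these differences stays open. Positions of the BACs were not used here, so whether they lie together was not tested.

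Overlaps of the 5% most extreme BACs were tested for all 342 combinations of 2 tertiary clones from different families and a direction, by Fisher's exact test, 1-sided. With Benjamini-Hochberg adjustment, 69 passed 0.05, 35 of them for higher and 34 for lower BACs. Of these 69, 45 involved a pair scanned in different batches. Among the 198 combinations without such a pair 24 passed. The most shared BACs were those of 14-39 and 9-90 (74, where 7.34 were expected) and of 2-41 and 14-39. The test treats BACs as independent, which they need not be. Clones of 1 family also share the array of their primary clone, so the 342 tests are not independent. The 69 are therefore no count of separate shared changes.

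The BACs lower in clone 1-13 had a positive median log2 in clone 2-41. There no BAC was called higher than in its primary clone, though some were against all arrays outside its family. Against all arrays outside its family, 25 BACs were lower in 1-13, with a median log2 of -0.53 (SD 0.13 over BACs). The same BACs had a median of 0.33 (SD 0.17) in 2-41, a clone looked at because it was high, and of -0.0015 in primary clone 1. None of them was among the 72 BACs above (0 shared).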
